A study of Mus musculus with 24 samples.

How the data were processed

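Messenger RNA of mouse gastrocnemius, the large calf muscle, was measured by RNA sequencing in 24 libraries. The labels give 6 groups of 4, a control group and groups taken 1, 3, 5, 7 and 14 days after denervation, the loss of the motor nerve. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was enriched with oligo(dT) beads, libraries were made with a NEBNext Ultra kit, and sequencing was on an Illumina NovaSeq6000. The same protocol text names dorsal root ganglion neurons as the source of the RNA, while the tissue label of every library says gastrocnemius. The groups were taken from the tissue and title labels, and sensory neuron genes were fixed as one of the gene lists for this reason. Nothing in the labels says that the 4 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

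The authors deposited 1 table of 21965 mouse genes with Ensembl identifiers, which holds expected counts and TPM for each library, per the file headers. Expected counts are estimates that share ambiguous reads among genes and need not be whole, and 7.01% of the deposited expected counts were not whole numbers. They were rounded to whole numbers before testing. The deposited TPM values, named so in the file headers, were used only to describe Acta1. The aligner, the quantification software, the genome build and the use of read strand are not given in the sources used here. Of the identifiers, 21806 matched the GENCODE M21 annotation of GRCm38, from which all coordinates below are taken, 1-based, and which may not be the authors' build. Genes with near-identical copies (Mup18, Orm1 and Orm2, Hspa1a and Hspa1b, the globins, the immunoglobulin genes) and overlapping or antisense genes (Zfp593os) are uncertain, because the counting could move reads between copies or strands.

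Library totals ran from 16082839 to 20696876 counts, and 3699 genes had no count in any library. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling and its default expression filter, which left 14246 genes. All 24 libraries entered one quasi-likelihood fit with 1 coefficient per group, and 9 two-sided contrasts were tested, each day against control and each day against the day before it in the series, plus an omnibus test over the 6 groups. Adjusted p-values are Benjamini-Hochberg values, and a gene is said to have risen, fallen or changed where its adjusted p was below 0.05. Log2 fold changes are those of the quasi-likelihood fit and are shown with their standard errors. A prior count of 2 was used for the log2 CPM of list tests and principal components, not for the fold changes. CPM, the count scaled to library size after TMM, is shown as mean ± SD with n = 4 libraries per group. A fold against a group whose libraries were all at 0 is given as a lower bound against 3 counts over the group, and a group with 1 to 3 counts gives a ratio with its 95% counting interval. Bounds and intervals cover counting error only and take each count as an independent read.

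Gene lists (39, for muscle, metabolic, stress and immune pathways and for cell types that muscle can hold), 34 key genes and the rule for naming genes were fixed before the data were examined. The rule took, per day, the 6 largest rises and 6 largest falls among genes that passed, with a mean log2 CPM of at least 1 and with all 4 denervated libraries beyond all 4 control libraries. Unnamed gene models were skipped, and some genes that the rule named are not reported here. It also took up to 4 members per list with the largest change at any day, and the 4 largest rises and 4 largest falls between neighbouring times. Whether a list shifted relative to all other genes was tested with camera of limma 3.58.1 (preset correlation between genes 0.01) over 195 pairs of list and day, and repeated with an estimated correlation and with fry, which asks whether the members move one way without comparing them with other genes. Counts of list members adjusted over the list alone were the same as over all genes in 187 of the 195 pairs and are printed where they differ.

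The programs were tested on simulated counts for day 1 against control with 13386 genes. edgeR found 8 of 48 genes changed 1.1-fold, 24 of 47 changed 1.25-fold, 44 of 50 changed 1.5-fold and 43 of 48 changed 2-fold, and called 6 of 13162 unchanged genes. DESeq2 found 8, 24, 44 and 44 and called 10. Of the log2 fold changes, 94.3% lay within 2 standard errors of the simulated value. The omnibus test called 8 unchanged genes, and camera called the list that had been raised 1.25-fold (31 members) and 1 other list. The simulation changed few genes, kept control levels for all others in every group and drew genes independently. It therefore does not test TMM or camera where most genes change or list members move together.

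The alternatives were size factors of DESeq2 in edgeR, DESeq2 1.42.0 itself, no filter, a filter of CPM of at least 1 in at least 4 libraries, the replicate number as a block, a fold threshold, removal of mitochondrial and the 20 most abundant genes, fits of only the groups compared, and leaving out each of the 24 libraries. Scaling by library totals alone, and fits without the libraries labelled day 1 and 3 or day 1 and 5, were chosen after seeing the data. No library and no column of the table was left out of the main tests.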

Results

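The libraries hold the transcriptome of mouse gastrocnemius without denervation and at 5 times after it, and the series concerns signals that denervated muscle sends back to neurons. Each group has 4 libraries, and library totals ran from 16082839 to 20696876 counts. Libraries of a group lay close together, with a common biological coefficient of variation of 0.0389. The mean chi-square per gene was 2.02 to 4.26 over 36 pairs within groups, above counting noise if each count is an independent read. The 20 most abundant genes held 35.1 ± 0.22% of control counts (SD, n = 4) and 23 ± 0.043%, 24.3 ± 0.045%, 19.9 ± 0.049%, 17.2 ± 0.009% and 16.8 ± 0.016% in the libraries labelled day 1, 3, 5, 7 and 14. Acta1, the skeletal muscle actin gene, stood at 69774 ± 1265 TPM in control and 24724 ± 246 TPM at day 14. Scaling by library totals alone, without TMM, placed the median gene above control by 0.614, 0.344, 0.674, 0.814 and 0.778 (log2) at days 1, 3, 5, 7 and 14. All changes below are therefore relative to the bulk of genes. With library totals alone, 11 of the 119 list shifts and 9 of the 380 named changes that passed had the opposite sign, and these are named where they are reported. Some other list shifts kept their sign but nearly vanished. Among them were excitation-contraction coupling at day 1 (median −0.58 with TMM and −0.002 without) and pericyte markers at day 3 (−0.43 and −0.05).

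**Figure D1:**
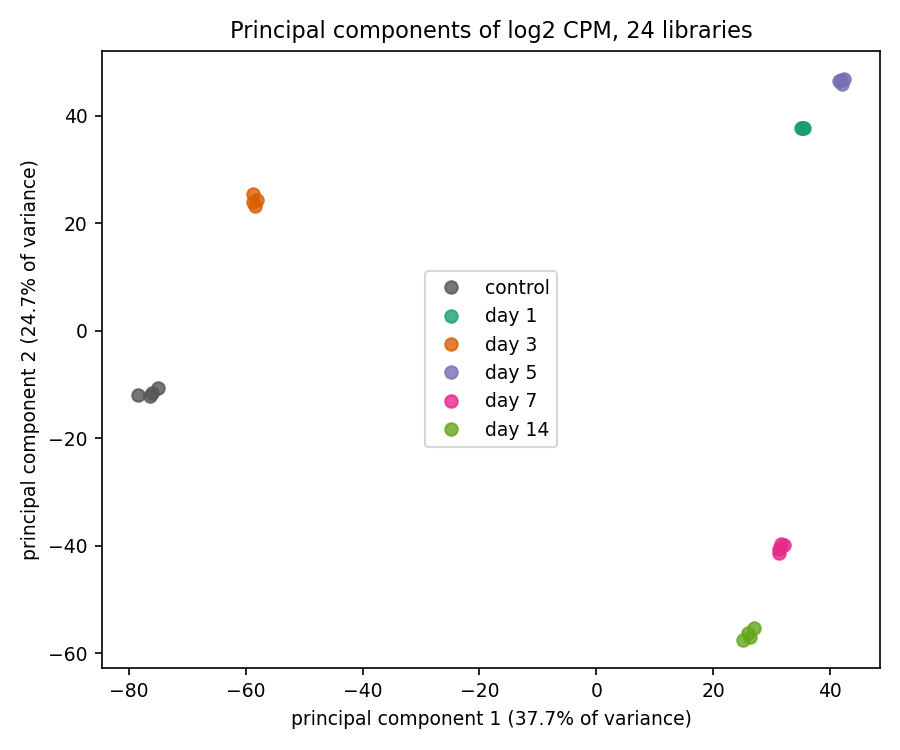
Principal components 1 (37.7% of variance) and 2 (24.7%) of log2 CPM for the 24 libraries, 1 point per library and colour by labelled group. On component 1 the libraries labelled day 3 (−58.8 to −58.1) lay next to control (−78.5 to −75.1), while all other denervated libraries lay between 25.2 and 42.5. On component 3 (14.7%, not drawn) they lay apart, with labelled day 3 at 50.3 to 51.2 and control at −45.1 to −43.5.

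Day 1 against control asked how the muscle responded first. In the libraries labelled day 1, genes of the muscle fibre that respond to lost nerve contact were already high. Chrng, the fetal gamma subunit of the acetylcholine receptor (ENSMUSG00000026253, chromosome 1, 87204657 to 87212694, plus strand), rose 116-fold (log2 6.86 ± 0.13, from 0.374 ± 0.17 to 44.4 ± 3.1 CPM, n = 4 per group). Chrna1 rose 10.9-fold (log2 3.45 ± 0.033) and Musk, the receptor kinase that organises the neuromuscular junction, rose 9.12-fold (log2 3.19 ± 0.06). Myog, a myogenic transcription factor (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, plus strand), rose 5.94-fold (log2 2.57 ± 0.056) and Gadd45a, a growth arrest gene (ENSMUSG00000036390, chromosome 6, 67035096 to 67037457, minus strand), rose 4.46-fold (log2 2.16 ± 0.032). The ubiquitin ligase genes Trim63 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629, plus strand) and Fbxo32 (ENSMUSG00000022358, chromosome 15, 58175879 to 58214932, minus strand), which mark many forms of atrophy, fell 3.7-fold (log2 −1.89 ± 0.027, from 3030 ± 110 to 819 ± 28 CPM) and 3.84-fold (log2 −1.94 ± 0.018, from 2210 ± 27 to 576 ± 7.8 CPM). Each of these changes had an edgeR adjusted p of at most 3.7e-37. Every day was compared with the same control libraries, so a high level in control alone would appear as a fall at every day. Whether Trim63, Fbxo32 or other genes below control at every day were raised in the control libraries was not tested. Their falls are therefore differences from these control libraries and need not be responses to denervation.

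In the acetylcholine receptor and neuromuscular junction list, 9 of 14 measured members rose, 4 fell and 1 did not pass (camera adjusted p = 0.017, and adjusted p = 0.069 with an estimated correlation). Among myogenic transcription factors and denervation-linked repressors, 7 of 12 measured members rose, 3 fell and 2 did not pass (adjusted p = 0.03), with Runx1 up 7.88-fold and Hdac4 up 2.23-fold. The list of atrophy-linked ubiquitin ligases and FoxO factors went down: 0 of 13 measured members rose, 12 fell and 1 did not pass (adjusted p = 2e-05). Contractile genes fell, with all 12 measured members down in the fast fibre list (adjusted p = 1.8e-10). In the slow fibre list all 12 measured members fell (adjusted p = 4.2e-09). Myl2 fell 19-fold (log2 −4.24 ± 0.047) and Myh7, the slow myosin heavy chain, fell 12.4-fold (log2 −3.63 ± 0.035). Energy metabolism fell with them. Of the nuclear-encoded oxidative phosphorylation subunits, all 72 measured members fell (median log2 −1.02, adjusted p = 9.5e-26). The tricarboxylic acid cycle and pyruvate dehydrogenase list had all 16 measured members down (adjusted p = 2e-11), Idh2 by 9.19-fold. In fatty acid uptake and oxidation all 20 measured members fell (adjusted p = 6.9e-14). In glycolysis and glycogen breakdown, 1 of 17 measured members rose, 16 fell and 0 did not pass (median log2 −1.52, adjusted p = 2.2e-11). The mitochondrial biogenesis and dynamics list fell as well: 2 of 15 measured members rose, 10 fell and 3 did not pass (adjusted p = 0.0096), with a median of −0.38 that was 0.20 with library totals alone.

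Cells other than fibres moved strongly in the same libraries. Lymphocyte markers were high, since all 12 measured members rose (median log2 5.27, adjusted p = 2.1e-05). Cd8a, a T cell surface gene, stood 181-fold (95% counting interval 49.9 to 1500) above control, and at least 91.3-fold without control replicate 1. Glycam1, an adhesion ligand made by the vessels of lymph nodes (ENSMUSG00000022491, chromosome 15, 103562759 to 103565081, minus strand), was not counted in any control library and stood at 42.8 ± 1.8 CPM, at least 686-fold higher. Cd5l (at least 113-fold) and Orm2 (at least 98.9-fold) were likewise at 0 in control. Mup18 stood 1210-fold (95% counting interval 217 to 47800) higher and at least 302-fold without control replicate 2. Trdc, a gamma-delta T cell receptor gene, stood 760-fold (95% counting interval 136 to 30000) higher and at least 190-fold without control replicate 2. Zfp593os stood 714-fold (95% counting interval 128 to 28200) higher and at least 180-fold without control replicate 1. Macrophage markers rose together (all 17 measured members rose, adjusted p = 5.5e-08), Adgre1, a macrophage surface gene, by 2.34-fold. Among neutrophil markers, all 8 measured members rose (adjusted p = 0.00094). Repair Schwann cell markers, genes of glia that have lost their axon, rose (all 6 measured members rose, adjusted p = 0.0023): Shh stood at least 67.2-fold above control and Ngfr rose 4.55-fold. Sox2 rose 15.7-fold and 43.6-fold (95% counting interval 11.9 to 363) without control replicate 1. Adipocyte markers rose (6 of 7 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.00097), with Adipoq, the adipocyte hormone adiponectin, up 11-fold and Retn 27.3-fold. The globin genes and Alas2 of the erythroid list rose too, a measure of blood in the sample (all 5 measured members rose, median log2 1.97, adjusted p = 0.00016). Cell cycle genes rose beside the lymphocyte genes (20 of 21 measured members rose, 1 fell and 0 did not pass, adjusted p = 1.4e-05), Ccnb1 by 13.6-fold, Top2a by 8.34-fold and Aurkb by 8.03-fold. Endothelial markers fell: all 8 measured members fell (adjusted p = 3.9e-06).

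The 6 largest falls were Chrna2 (39.4-fold), Cimap1d (35.3-fold), Mettl21c (32.4-fold), Atp1b4 (32.4-fold), Myh6 (26.7-fold) and Depp1 (25.5-fold, from 368 ± 10 to 14.4 ± 1.1 CPM). Myh6, a cardiac myosin, fell 17.5-fold without control replicate 4. Its control libraries themselves ran from 0.964 to 22 CPM, with replicates 2 and 4 high, so its fold is unstable. In all, 10588 of 14246 genes changed, 5431 higher and 5157 lower, and 10050 higher and 1899 lower of 11949 with library totals alone. Under that scaling Cd81 (log2 −0.24), Rab27a (−0.57) and Fst (−0.46), which fell, stood at 0.34, 0.01 and 0.13.

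Day 3 against control asked which genes differed at the next time. In the libraries labelled day 3, Arg1, arginase of wound macrophages, rose 343-fold (log2 8.42 ± 0.19, from 0.145 ± 0.04 to 52.3 ± 3.4 CPM, n = 4 per group), Chil3 rose 243-fold (log2 7.93 ± 0.17) and 497-fold without control replicate 4, and S100a9, a neutrophil gene, rose 187-fold (log2 7.55 ± 0.21). The heat shock genes Hspa1b and Hspa1a rose 23.5-fold and 12.9-fold (log2 4.55 ± 0.081 and log2 3.69 ± 0.061). Chrng did not pass (0.563 ± 0.098 against 0.374 ± 0.17 CPM, adjusted p = 0.2). Chrna1 rose 1.14-fold (log2 0.18 ± 0.042), Musk rose 7.71-fold and Myog 6.66-fold. Myh3, embryonic myosin (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291, plus strand), fell 1.54-fold (log2 −0.63 ± 0.19), a call that did not hold without control replicate 4 (log2 −0.36).

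Every measured proteasome subunit rose: all 31 measured members rose (median log2 0.73, camera adjusted p = 1.1e-14), Psmb3 by 2.35-fold, Psmc4 by 2.16-fold, Psmd13 by 2.11-fold and Psmb2 by 2.07-fold. In the unfolded protein and integrated stress response list, 13 of 16 measured members rose, 3 fell and 0 did not pass (adjusted p = 0.00078). Inflammatory cytokines and chemokines rose (12 of 14 measured members rose, 1 fell and 1 did not pass (13 rose and 1 fell adjusted over the list alone), adjusted p = 2.7e-05). Cxcl5 was at 0 in control and stood at least 125-fold higher. Ccl7 rose 47.8-fold and Il1b rose 45-fold. Ccl4 stood 133-fold (95% counting interval 23.6 to 5280) higher and at least 33.3-fold without control replicate 4. Macrophage markers rose (15 of 17 measured members rose, 2 fell and 0 did not pass, adjusted p = 1.5e-05), Fcgr1 by 15-fold and Itgam by 9.33-fold. Neutrophil markers rose as well (7 of 8 measured members rose, 0 fell and 1 did not pass, adjusted p = 5e-04). Lymphocyte markers did not shift: 0 of 12 measured members rose, 2 fell and 10 did not pass (0 rose and 0 fell adjusted over the list alone) (adjusted p = 0.86). Erythroid markers fell together (all 5 measured members fell, median log2 −2.02, adjusted p = 3.9e-05), Hbb-bt by 5.6-fold, Hbb-bs by 4.19-fold and Hba-a2 by 4.04-fold.

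Vesicle genes, the subject of the series, rose in these libraries. In the extracellular vesicle biogenesis and release list, 17 of 26 measured members rose, 4 fell and 5 did not pass (adjusted p = 0.012), with Cd63, a tetraspanin of exosomes, up 2.8-fold (log2 1.49 ± 0.026, from 142 ± 4.4 to 399 ± 5.7 CPM) and Hgs, a component of the sorting machinery of multivesicular bodies, up 2.5-fold. Rab27a, which guides vesicle release, fell 2.34-fold (log2 −1.22 ± 0.11), and Cd81 fell 1.2-fold (log2 −0.27, and 0.11 with library totals alone). Matrix genes fell. In the extracellular matrix list, 4 of 21 measured members rose, 17 fell and 0 did not pass (adjusted p = 0.00017), Col3a1 by 3.33-fold and Postn by 6.57-fold against control libraries that themselves ran from 41.8 to 260 CPM. Among fibro-adipogenic progenitor and fibroblast markers, 1 of 10 measured members rose, 8 fell and 1 did not pass (adjusted p = 0.0047), and Ly6a rose 1.97-fold. The median of this list was −0.45, and −0.08 with library totals alone. Of the myelinating Schwann cell markers, 1 of 10 measured members rose, 9 fell and 0 did not pass (adjusted p = 0.0047). Neuromuscular junction and myogenic lists did not pass here (adjusted p = 0.8 and adjusted p = 0.45). In the cell cycle list 6 of 21 measured members rose, 12 fell and 3 did not pass (6 rose and 14 fell adjusted over the list alone) (adjusted p = 0.13), Ccna2 down 8.43-fold and 14.9-fold without day 3 replicate 3. Ppargc1a, a regulator of mitochondrial biogenesis, rose 2.19-fold. In the nuclear oxidative phosphorylation list 0 of 72 measured members rose, 68 fell and 4 did not pass (0 rose and 70 fell adjusted over the list alone) (median log2 −0.40, adjusted p = 2.7e-13, and adjusted p = 0.051 with an estimated correlation). That median was −0.03 with library totals alone. In repair Schwann cell markers, 1 of 6 measured members rose, 1 fell and 4 did not pass, with a median log2 of 0.13 as fitted and 0.09 with members at 0 in control set to their bound.

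Among the largest falls were Gbp10 (45.1-fold), Pdk4, a kinase that restrains glucose oxidation (27.5-fold, from 4690 ± 64 to 170 ± 4.3 CPM), Depp1 (22.8-fold), Atcay (13.2-fold) and Glcci1 (12.8-fold). The remaining large rises, of Zfp593os (422-fold (95% counting interval 75.5 to 16700), and at least 106-fold without control replicate 1), Orm2 (at least 15.7-fold) and Mup18 (140-fold (95% counting interval 24.7 to 5540), and at least 34.9-fold without control replicate 2), were of genes near 0 in control. In total 9997 genes changed, 4910 higher and 5087 lower, and 7823 higher and 2595 lower of 10418 with library totals alone.

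At day 5 the fibre response stood beside a strong lymphoid signal. Gadd45a rose 10.9-fold (log2 3.44 ± 0.031, from 64.9 ± 4.6 to 707 ± 9.8 CPM, n = 4 per group) and Myh3 rose 32.2-fold (log2 5.01 ± 0.086). Gdf5, a BMP family ligand that limits denervation atrophy, rose 98.6-fold (log2 6.62 ± 0.18, from 0.295 ± 0.15 to 29.4 ± 1.5 CPM). Actc1, cardiac actin, fell 41.7-fold (log2 −5.38 ± 0.03, from 4140 ± 140 to 99.1 ± 4.8 CPM). Trim63 and Fbxo32 fell 1.27-fold and 1.41-fold, but with library totals alone stood at log2 0.3 and 0.15. These edgeR adjusted p-values were at most 1.2e-16.

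Developmental and cardiac sarcomere isoforms rose as a list (6 of 7 measured members rose, 1 fell and 0 did not pass, camera adjusted p = 0.0094, and adjusted p = 0.059 with an estimated correlation), with Ankrd1, a stretch-responsive gene, at 466 against 3.77 CPM, Myh8 up 18.8-fold and Actc1 as the member that fell. All 13 mitochondrially encoded subunits fell (adjusted p = 1.2e-07, and adjusted p = 0.09 with an estimated correlation), mt-Co1 by 2.99-fold and mt-Co3 by 2.62-fold. Among the nuclear-encoded subunits all 72 measured members fell (adjusted p = 3e-28), Sdhb by 3.39-fold. In glycolysis and glycogen breakdown 1 of 17 measured members rose, 16 fell and 0 did not pass (median log2 −1.94, adjusted p = 4.2e-13). The mitochondrial biogenesis and dynamics list fell (2 of 15 measured members rose, 7 fell and 6 did not pass, adjusted p = 0.044, and adjusted p = 0.069 with an estimated correlation), a call that ended without day 5 replicate 2 and whose median of −0.31 was 0.33 with library totals alone. Atrophy-linked ligases and FoxO factors also fell (2 of 13 measured members rose, 10 fell and 1 did not pass, adjusted p = 0.013), with a median of −0.35 and of 0.30 with library totals alone. Among activin, myostatin and BMP genes 8 of 16 measured members rose, 6 fell and 2 did not pass and the list did not pass (adjusted p = 0.66), although Acvr2b, an activin receptor, fell 6.48-fold. In p53 targets and growth arrest 8 of 14 measured members rose, 4 fell and 2 did not pass (8 rose and 5 fell adjusted over the list alone) (adjusted p = 0.2). Excitation-contraction coupling and membrane excitability genes fell (3 of 14 measured members rose, 11 fell and 0 did not pass, adjusted p = 0.00045). Pericyte and smooth muscle markers fell (all 8 measured members fell, adjusted p = 1.6e-05), Kcnj8 by 3.2-fold, Cspg4 by 2.63-fold and Pdgfrb by 2.46-fold. Tendon markers fell too (1 of 6 measured members rose, 5 fell and 0 did not pass, adjusted p = 0.017), Fmod by 3.51-fold. Bdnf fell 2.1-fold (log2 −1.07 ± 0.38), a call lost without control replicate 4 (log2 −0.85) or day 5 replicate 4 (log2 −0.83). Fst, a myostatin antagonist, fell 1.15-fold (log2 −0.2), stood at 0.45 with library totals alone, and did not pass without control replicate 2 (−0.18), control replicate 3 (−0.15) or day 5 replicate 1 (−0.18).

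Lymphocyte markers were again high (all 12 measured members rose, median log2 5.69, adjusted p = 1.6e-05). Cd79a of the B cell receptor rose 174-fold (log2 7.45 ± 0.18, from 0.273 ± 0.13 to 48.4 ± 4.5 CPM) and Ms4a1 rose 133-fold. Ighg3, an immunoglobulin gene, Glycam1, Cd5l, Bpifb1 and Orm2 were at 0 in control and stood at least 1210-fold, at least 825-fold, at least 388-fold, at least 334-fold and at least 123-fold higher. Marco, a scavenger receptor of macrophages in lymph nodes and spleen, rose 922-fold (log2 9.85 ± 0.21, from 0.0822 ± 0.095 to 83.3 ± 4.3 CPM). Neutrophil markers rose (all 8 measured members rose, adjusted p = 0.00049). S100a8 rose 161-fold and 556-fold (95% counting interval 154 to 4600) without control replicate 3, Ngp stood 806-fold (95% counting interval 144 to 31900) higher and at least 202-fold without control replicate 4. Camp stood 121-fold (95% counting interval 21.4 to 4800) higher and at least 29.9-fold without control replicate 3. Inflammatory genes rose beside them (13 of 14 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.0021; median log2 1.93 as fitted and 1.88 at the bound of the member at 0). So did cell cycle genes (19 of 21 measured members rose, 2 fell and 0 did not pass, adjusted p = 0.00097) and macrophage markers (all 17 measured members rose, adjusted p = 1.2e-08), Gpnmb by 5.84-fold. Erythroid markers fell (all 5 measured members fell, median log2 −1.61, adjusted p = 0.00027). Repair Schwann cell markers rose (all 6 measured members rose, adjusted p = 0.0029).

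Large falls besides Actc1 were of Chrna2 (36.1-fold), Smco1 (34.4-fold), Mlf1 (23.8-fold, from 341 ± 12 to 14.3 ± 0.35 CPM) and Myh6 (30.5-fold, and 20-fold without control replicate 4). The fold of Myh6 is again unstable, with control libraries from 0.964 to 22 CPM. Of the genes tested, 10585 changed, 5483 higher and 5102 lower, and 10291 higher and 1680 lower of 11971 with library totals alone.

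By day 7 the receptor and embryonic genes were far above control and the metabolic genes far below. Chrng rose 174-fold (log2 7.44 ± 0.12, from 0.374 ± 0.17 to 66.5 ± 1.4 CPM, n = 4 per group) and Ankrd1 149-fold (log2 7.22 ± 0.065). Gdnf, a neurotrophic factor for motor neurons, rose 28.8-fold (log2 4.85 ± 0.21, from 0.481 ± 0.091 to 14 ± 1.9 CPM), Igf1, a growth factor, 6-fold (log2 2.59 ± 0.054) and Cdkn1a, the cell cycle inhibitor p21, 5.91-fold (log2 2.56 ± 0.029). Fbp2, the muscle fructose bisphosphatase, fell 62.8-fold (log2 −5.97 ± 0.081, from 132 ± 7.4 to 2.11 ± 0.37 CPM) and Eno3, muscle enolase, fell 18.8-fold (log2 −4.24 ± 0.021). Trim63 fell 9.31-fold and Fbxo32 5.58-fold. All of these had edgeR adjusted p-values of at most 3e-25.

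In the acetylcholine receptor and neuromuscular junction list 9 of 14 measured members rose, 5 fell and 0 did not pass (median log2 1.92, camera adjusted p = 0.011, and adjusted p = 0.053 with an estimated correlation). Among myogenic factors 8 of 12 measured members rose, 3 fell and 1 did not pass (adjusted p = 0.0085). Glycolysis genes fell (1 of 17 measured members rose, 16 fell and 0 did not pass, adjusted p = 2.7e-12), Phka1 by 11.2-fold. Fatty acid genes fell too (all 20 measured members fell, adjusted p = 9.8e-13), Fabp3, which carries fatty acids in the cell, by 16.4-fold and Cpt1b, which admits them to mitochondria, by 11.6-fold. Nuclear-encoded oxidative phosphorylation subunits were down (all 72 measured members fell, adjusted p = 4.1e-23), Cox7a1 by 8.77-fold. The mitochondrially encoded subunits fell (all 13 measured members fell, adjusted p = 8.3e-06, and adjusted p = 0.15 with an estimated correlation), though their median of −0.71 was 0.06 with library totals alone. Mitochondrial biogenesis and dynamics genes fell (2 of 15 measured members rose, 10 fell and 3 did not pass, adjusted p = 0.011; median −0.39, and 0.37 with library totals alone), Pink1 and Mfn2 by 3.36-fold and 2.62-fold, while Dnm1l, which divides mitochondria, rose 2.67-fold. Slow fibre genes fell (2 of 12 measured members rose, 10 fell and 0 did not pass, adjusted p = 0.0023; median −0.53, and 0.23 with library totals alone). Proteasome subunits were below control (5 of 31 measured members rose, 22 fell and 4 did not pass, adjusted p = 0.0078, and adjusted p = 0.059 with an estimated correlation), with a median of −0.19 that was 0.57 with library totals alone. Autophagy and lysosome genes went both ways (9 of 19 measured members rose, 9 fell and 1 did not pass, adjusted p = 0.51), Gabarapl1, Tfeb and Bnip3 falling 3.79-fold, 3.55-fold and 3.48-fold.

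Endothelial markers fell (all 8 measured members fell, adjusted p = 1.2e-05), Cldn5, a tight junction gene of vessels, by 13.2-fold, Cdh5 by 3.53-fold and Pecam1 by 3.37-fold. Pericyte and smooth muscle markers fell (0 of 8 measured members rose, 7 fell and 1 did not pass, adjusted p = 0.0041; median −0.43, and 0.34 with library totals alone). Matrix genes rose (15 of 21 measured members rose, 5 fell and 1 did not pass, adjusted p = 0.0099, and adjusted p = 0.11 with an estimated correlation), Timp1, an inhibitor of matrix proteases, by 21.8-fold. Cell cycle genes rose (19 of 21 measured members rose, 0 fell and 2 did not pass, adjusted p = 6e-05). Macrophage markers rose (16 of 17 measured members rose, 0 fell and 1 did not pass, adjusted p = 4.9e-07), Ccr2 by 6.15-fold. Lymphocyte markers did not shift (3 of 12 measured members rose, 1 fell and 8 did not pass, adjusted p = 0.85). In neurotrophic and muscle-secreted factors 12 of 21 measured members rose, 5 fell and 4 did not pass and the list did not pass (adjusted p = 0.1). Satellite cell markers did not pass either: 1 of 8 measured members rose, 6 fell and 1 did not pass (2 rose and 6 fell adjusted over the list alone) (adjusted p = 0.29). Adipocyte markers rose (6 of 7 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.0034), Plin1, the coat protein of lipid droplets, by 34.3-fold. Erythroid markers fell (all 5 measured members fell, adjusted p = 0.00044). All 6 repair Schwann cell markers rose (adjusted p = 0.01; median log2 3.12 as fitted and 2.7 with members at 0 at their bound), Olig1, a glial transcription factor, standing at least 51.4-fold above control.

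The other named rises were of Bpifb1 (at least 423-fold), Agmat (at least 82.3-fold), Orm2 (at least 39.4-fold), Mup18 (539-fold (95% counting interval 96.6 to 21300), and at least 135-fold without control replicate 2) and Orm1 (280-fold (95% counting interval 95.7 to 1360), and 632-fold (95% counting interval 113 to 25000) without control replicate 4). The largest falls included Cimap1d (508-fold (95% counting interval 173 to 2470), and 1130-fold (95% counting interval 203 to 44800) without day 7 replicate 1), Depp1 (162-fold), Chrna2 (98.5-fold, and 207-fold (95% counting interval 70.5 to 1010) without day 7 replicate 2), Acot1 (66.6-fold) and Arrdc2 (50.3-fold). Cd81 fell 1.11-fold (log2 −0.15, and 0.61 with library totals alone). Day 7 had 10952 changed genes, 5723 higher and 5229 lower, and 10600 higher and 1732 lower of 12332 with library totals alone.

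At day 14 Chrng, Chrnd and Chrna1 stood at their highest of the 6 groups. Chrng reached 291 ± 5.4 CPM, 761-fold above control (log2 9.57 ± 0.093, n = 4 per group), Chrnd rose 99.4-fold (log2 6.64 ± 0.05) and Chrna1 28.3-fold (log2 4.82 ± 0.032). Myod1 and Runx1, transcription factors of muscle, rose 22.6-fold (log2 4.5 ± 0.054) and 19.7-fold (log2 4.3 ± 0.046). Sln, sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum, rose 102-fold (log2 6.67 ± 0.036, from 16.4 ± 0.83 to 1680 ± 26 CPM). Mybpc2, the fast isoform of myosin binding protein C, fell 82.1-fold (log2 −6.36 ± 0.024, from 10100 ± 100 to 123 ± 6.5 CPM), and Trim63 and Fbxo32 fell 25.1-fold (log2 −4.65 ± 0.031) and 20.2-fold (log2 −4.34 ± 0.021). No edgeR adjusted p among these exceeded 4.5e-48.

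The junction list shifted up (9 of 14 measured members rose, 4 fell and 1 did not pass, camera adjusted p = 0.0062). So did the myogenic list (8 of 12 measured members rose, 3 fell and 1 did not pass, adjusted p = 0.0058), where Dach2, a repressor of denervation genes, fell 20.3-fold and 86.1-fold (95% counting interval 14.9 to 3450) without day 14 replicate 4. Atrophy-linked ligases and FoxO factors fell (2 of 13 measured members rose, 10 fell and 1 did not pass, adjusted p = 0.00044). Fast fibre genes fell (1 of 12 measured members rose, 11 fell and 0 did not pass, adjusted p = 9.4e-08), Myh4, the fastest myosin heavy chain, by 7.74-fold and Atp2a1 by 6.66-fold, whereas Myh2 rose 1.9-fold. Slow fibre genes went both ways and did not pass (6 of 12 measured members rose, 4 fell and 2 did not pass, adjusted p = 0.62), Myh7 up 1.11-fold. Developmental and cardiac sarcomere isoforms rose (6 of 7 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.019, and adjusted p = 0.091 with an estimated correlation), Myh3 by 127-fold and Myh8 by 32.5-fold. In excitation-contraction coupling and membrane excitability 3 of 14 measured members rose, 10 fell and 1 did not pass (adjusted p = 0.0018), and Kcnn3, the channel of the afterhyperpolarisation of denervated fibres, rose 18.8-fold. Oxidative phosphorylation genes were still below control, nuclear-encoded (all 72 measured members fell, adjusted p = 4e-22) and mitochondrially encoded (0 of 13 measured members rose, 12 fell and 1 did not pass, adjusted p = 0.00033, and adjusted p = 0.23 with an estimated correlation; median −0.57, and 0.15 with library totals alone). Glycolysis genes fell furthest (median log2 −2.69, adjusted p = 2.7e-13), Pygm, muscle glycogen phosphorylase, by 15.6-fold. Proteasome subunits were lower (8 of 31 measured members rose, 22 fell and 1 did not pass, adjusted p = 0.0058, and adjusted p = 0.051 with an estimated correlation), with a median of −0.29, and 0.43 with library totals alone. Cytosolic ribosomal protein genes rose (68 of 75 measured members rose, 2 fell and 5 did not pass, median log2 0.31, adjusted p = 5.5e-10, and adjusted p = 0.16 with an estimated correlation), Rpl3 by 2.48-fold. Gdf6, a BMP ligand, rose 26.8-fold and 41.8-fold without control replicate 2, and Mstn, the growth inhibitor myostatin, fell 5.01-fold.

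Matrix genes rose (18 of 21 measured members rose, 3 fell and 0 did not pass, adjusted p = 1.1e-05), Col1a1, the main fibrillar collagen, by 2.03-fold (log2 1.02 ± 0.019, from 1310 ± 11 to 2660 ± 40 CPM), and Lum rose 3.62-fold in a fibroblast list that did not pass (adjusted p = 0.51). Tendon markers rose (5 of 6 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.044, and adjusted p = 0.067 with an estimated correlation). Myelinating Schwann cell markers fell (1 of 10 measured members rose, 7 fell and 2 did not pass, adjusted p = 0.0042), Ncmap by 63-fold, Prx by 14.1-fold and Mbp by 8.72-fold. Repair Schwann cell markers rose (all 6 measured members rose, adjusted p = 0.0058; median log2 3.12 as fitted and 3.07 at the bounds). Of 19 sensory neuron markers only 7 were measured, and the list did not pass (3 of 7 measured members rose, 2 fell and 2 did not pass, adjusted p = 0.52), although Uchl1, a neuronal ubiquitin hydrolase, rose 11.9-fold. Adipocyte markers rose (6 of 7 measured members rose, 1 fell and 0 did not pass, adjusted p = 0.013, and adjusted p = 0.056 with an estimated correlation). Erythroid markers were above control (all 5 measured members rose, median log2 1.5, adjusted p = 0.00052). In lymphocyte markers 4 of 12 measured members rose, 2 fell and 6 did not pass (1 rose and 2 fell adjusted over the list alone) (adjusted p = 0.84). Pericyte and smooth muscle markers fell (all 8 measured members fell, adjusted p = 0.0047; median −0.26, and 0.46 with library totals alone). In vesicle genes 11 of 26 measured members rose, 14 fell and 1 did not pass and the list did not pass (adjusted p = 0.77), with Rab27b up 6.04-fold and Rab27a down 3.19-fold. Cd81 stood at log2 −0.08 (adjusted p = 0.01), at −0.06 and not past the threshold without day 14 replicate 2, and at 0.64 with library totals alone. In neurotrophic and muscle-secreted factors 12 of 21 measured members rose, 4 fell and 5 did not pass (adjusted p = 0.11). Cntf, a Schwann cell factor, fell 8.42-fold, and Gdf15, a stress hormone, rose 7.11-fold and 13.9-fold (95% counting interval 3.69 to 117) without control replicate 3.

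Further named rises were of Bpifb1 (at least 616-fold), Olig1 (at least 64-fold), Agmat (at least 27.5-fold), Ighg2c (212-fold) and Orm2 (at least 23.4-fold). Chrna2 fell to 0.0133 CPM, 826-fold (95% counting interval 147 to 32700) below control and at least 210-fold without day 14 replicate 1, and Cimap1d (198-fold), Chac1 (71.6-fold) and Depp1 (71-fold) fell as well. At this time 10606 genes changed, 5579 higher and 5027 lower, and 10604 higher and 1670 lower of 12274 with library totals alone.

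**Figure D2:**
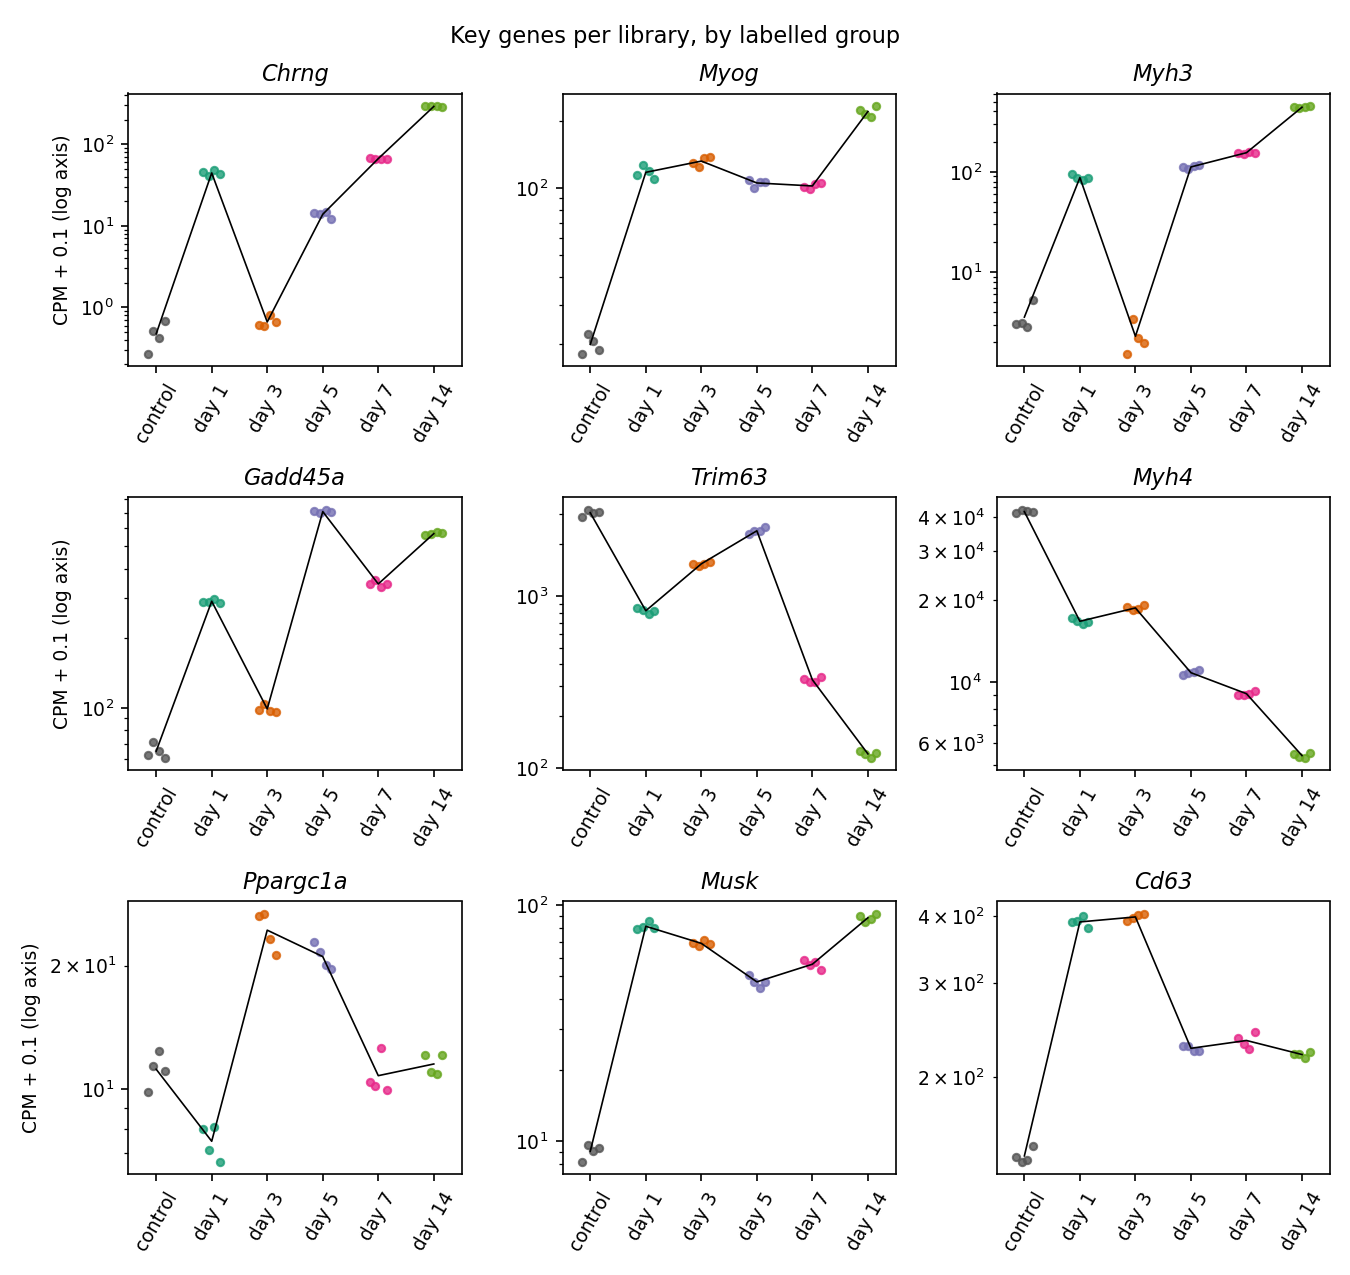
CPM plus 0.1 on a log axis for 9 key genes, 1 point per library, by labelled group (4 libraries each), with a line through the group means. Chrng stood at 0.563 ± 0.098 CPM in the libraries labelled day 3 and at 44.4 ± 3.1 CPM in those labelled day 1, and Trim63 was below control in all 5 denervated groups.

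**Figure D3:**
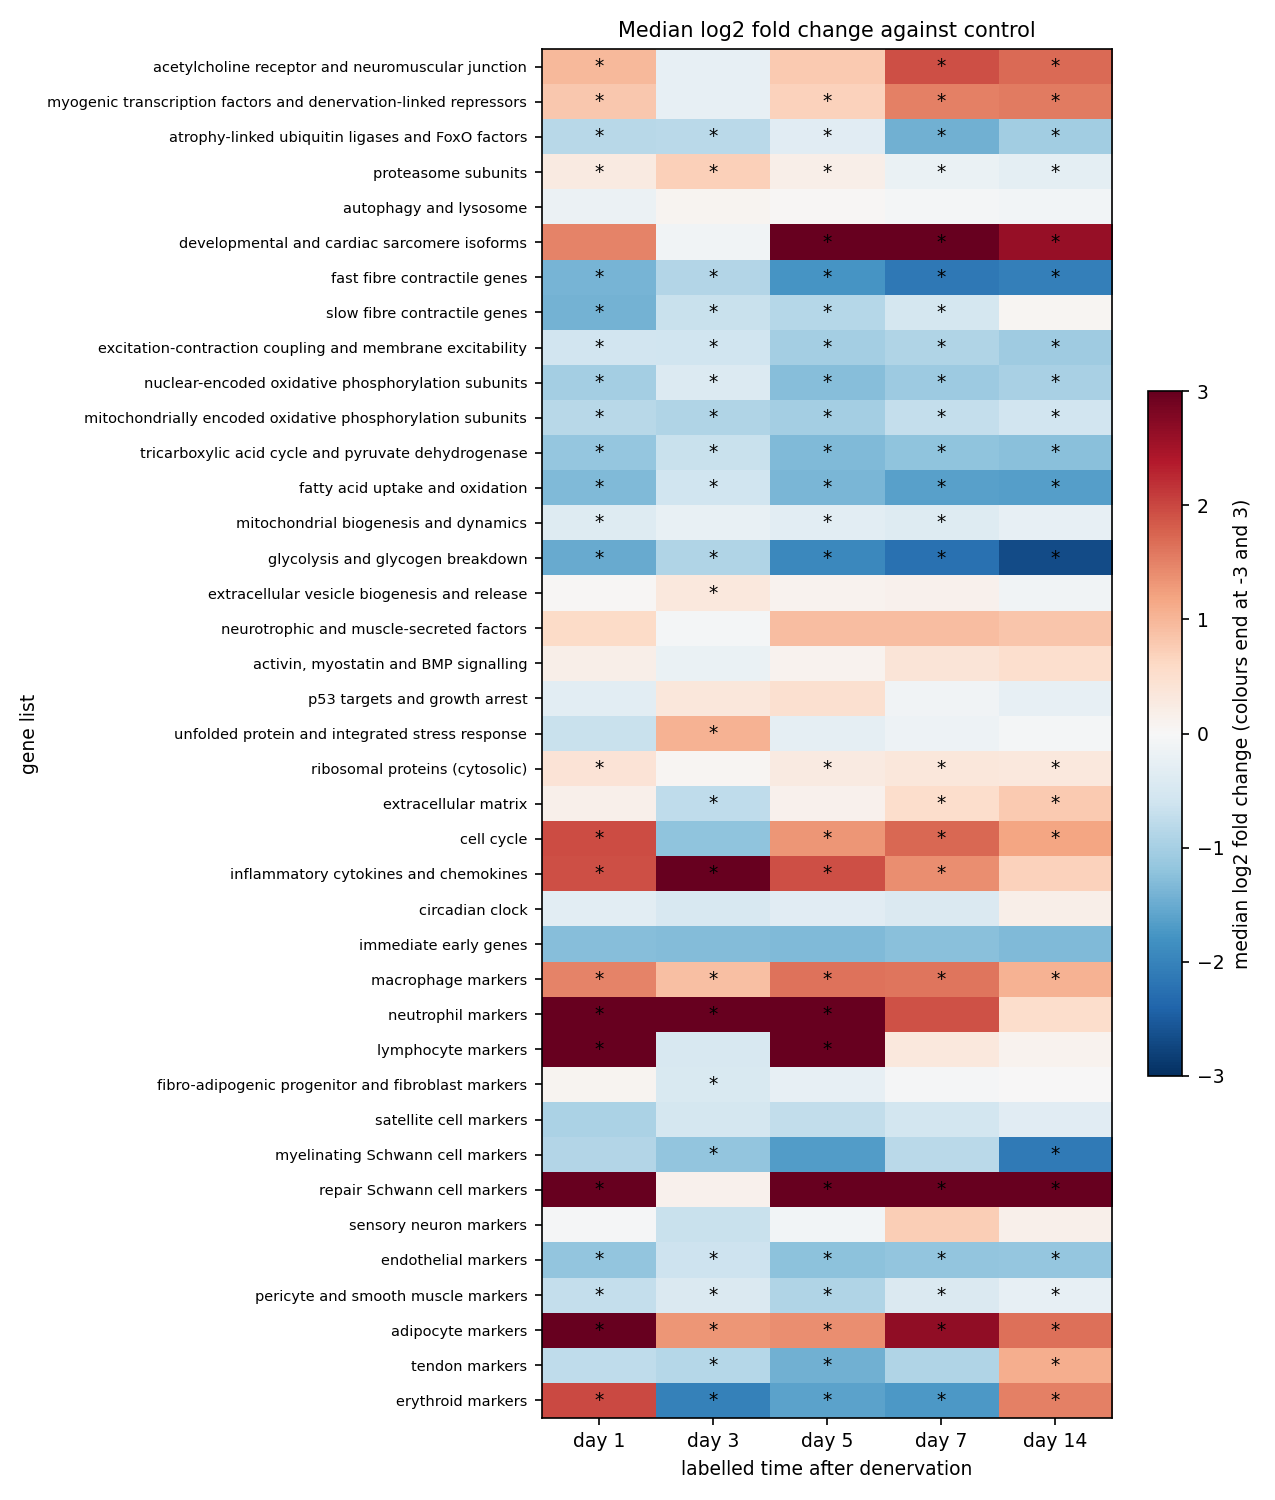
Median log2 fold change against control of the measured members of 39 gene lists (down) at 5 labelled times (across), with an asterisk where camera's adjusted p was below 0.05. Nuclear-encoded oxidative phosphorylation genes lay below control at all 5 times (medians −1.02, −0.40, −1.28, −1.10 and −0.97), and lymphocyte markers lay far above it at days 1 and 5 (5.27 and 5.69). With library totals alone the oxidative phosphorylation median at day 3 was −0.03.

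**Figure D4:**
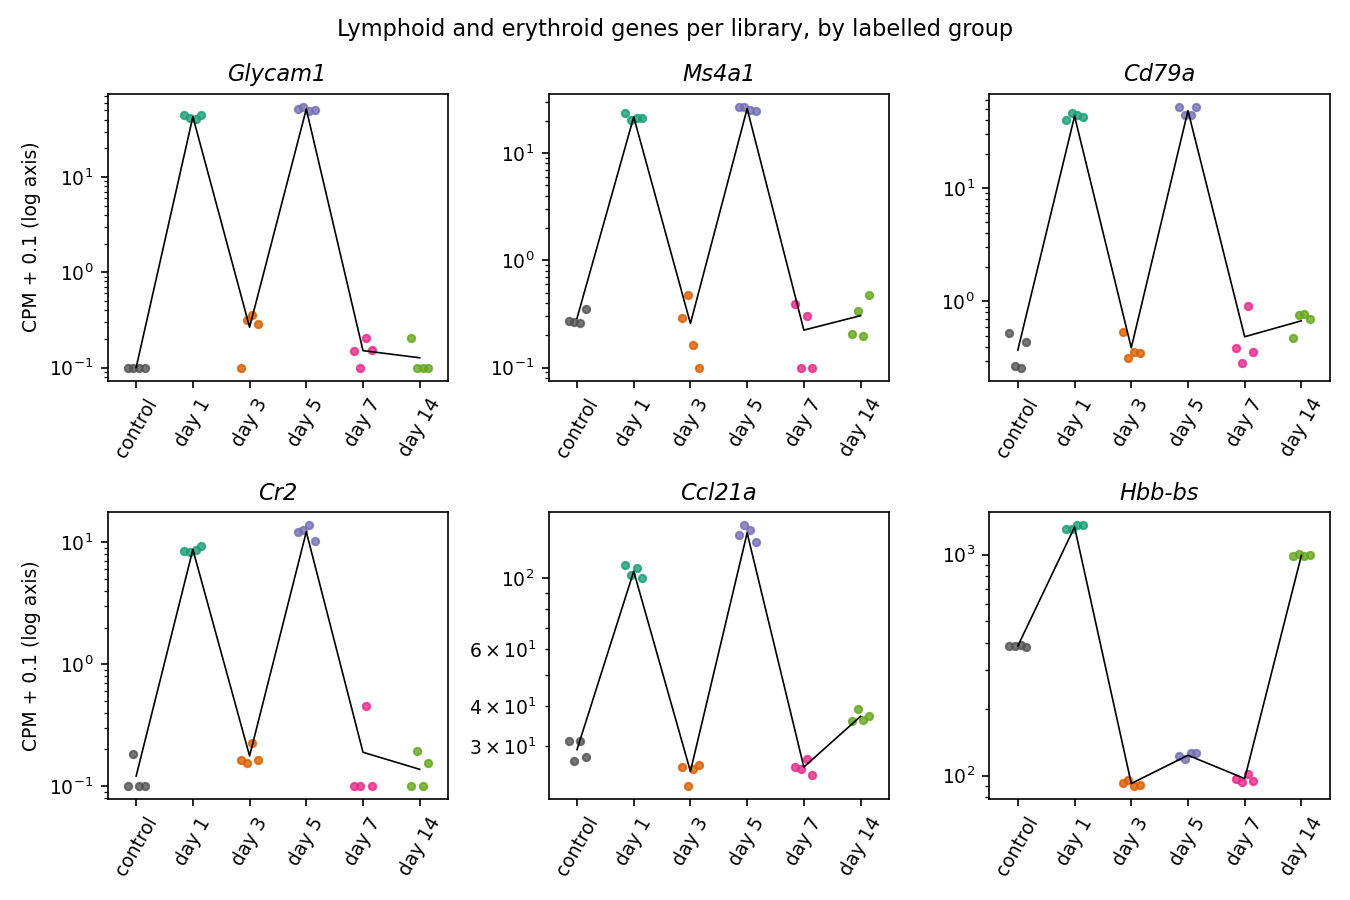
CPM plus 0.1 on log axes for 5 genes of lymphocytes and lymphoid tissue and the globin gene Hbb-bs, 1 point per library and a line through the group means. Glycam1 stood at 42.8 ± 1.8 and 51.5 ± 2.5 CPM in the libraries labelled day 1 and day 5 and at or below 0.165 ± 0.11 CPM in the other groups.

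Neighbouring times were compared with each other as contrasts of the same 24-library fit. From the libraries labelled day 1 to those labelled day 3, the heat shock genes Hspa1a and Hspa1b rose 41.4-fold (log2 5.37 ± 0.068) and 36.3-fold (log2 5.18 ± 0.079), Nr4a3, an early response gene, rose 33.9-fold and Chrna2 30.3-fold (n = 4 per group). Glycam1 fell 247-fold (log2 −7.95 ± 0.17), Olig1 was at 0 in the second group and at least 68.2-fold lower. Iglc2, an immunoglobulin gene, was 653-fold (95% counting interval 117 to 25800) lower and at least 165-fold without day 3 replicate 4. Fcer2a, a B cell gene, was 369-fold (95% counting interval 126 to 1790) lower and 841-fold (95% counting interval 151 to 33200) without day 3 replicate 4. The neuromuscular junction list was lower at the second label (median log2 −1.11, camera adjusted p = 0.00034), as were lymphocyte markers (median log2 −5.74, camera adjusted p = 4.9e-06). In all 10555 genes differed, 5139 higher and 5416 lower (3530 and 7260 with library totals alone). The median gene moved by −0.248, 0.26 and 0.128 (log2) under that scaling over the first 3 steps and by −0.034 over the last.

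From day 3 to day 5 the lymphoid genes returned. Ighg3 rose 589-fold (log2 9.2 ± 0.16, from 0.124 ± 0.055 to 75.4 ± 4.2 CPM, n = 4 per group), Iglc2 stood 1150-fold (95% counting interval 206 to 45500) higher and at least 291-fold without day 3 replicate 4. Fcer2a stood 419-fold (95% counting interval 143 to 2040) higher and 955-fold (95% counting interval 171 to 37800) without day 3 replicate 4, and Olig1 at least 77.3-fold. Gjb1, a gap junction gene of myelinating Schwann cells, fell 39.3-fold (log2 −5.3 ± 0.26), Chrna9 37.4-fold, Arg1 33-fold and Chrna2 27.8-fold. In this step 11017 genes differed, 5436 higher and 5581 lower (7353 and 3622 with library totals alone).

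From day 5 to day 7 they fell again: Glycam1 913-fold (log2 −9.83 ± 0.19, n = 4 per group), Marco 638-fold (log2 −9.32 ± 0.17), Ighg3 2030-fold (95% counting interval 695 to 9860) and 4640-fold (95% counting interval 833 to 183000) without day 7 replicate 4. The neutrophil gene Ngp was 1360-fold (95% counting interval 244 to 53700) lower and at least 345-fold without day 7 replicate 4. Aldh1a7 (41.4-fold), Tmem45b (32.1-fold), Aox2 (25.3-fold) and Chrna9 (24.5-fold) rose, and 9711 genes differed, 4812 higher and 4899 lower (6140 and 3790 with library totals alone). From day 7 to day 14 fewer genes passed, 7355, of which 3706 were higher and 3649 lower. Robo2 and Cntn2, cell surface genes of growing axons, rose 16.3-fold (log2 4.03 ± 0.13) and 12.4-fold (log2 3.64 ± 0.19), Nnat rose 12-fold and Ighg2c 28.5-fold. H2-Q10 fell 16.9-fold, Aldh1a7 15.5-fold and Chil3 16.5-fold, the last 38.3-fold without day 14 replicate 1.

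Over the whole series, 13782 of 14246 genes differed among the 6 groups by the omnibus test. The largest distance from control fell at day 1 for 1741 of them, at day 3 for 3255, at day 5 for 2911, at day 7 for 3184 and at day 14 for 2691. Bdnf, a neurotrophin, was lowest in the libraries labelled day 3 (0.205 ± 0.14 against 1.17 ± 0.34 CPM in control). Sdha and Cox4i1, nuclear subunits of the respiratory chain, were lowest at day 5 (305 ± 1.6 against 906 ± 17 CPM) and day 7 (274 ± 6.7 against 813 ± 10 CPM). By camera, 119 of the 195 pairs of list and day passed, 51 up and 68 down. The median, the mean and the test of a list differed in sign in 17 pairs: at day 1 the unfolded protein, sensory neuron and tendon lists, at day 3 the myogenic, autophagy, developmental sarcomere, neurotrophic, activin and p53 lists, at day 5 the autophagy, matrix and sensory neuron lists, at day 7 the p53 and fibroblast lists, and at day 14 the vesicle, p53 and lymphocyte lists. None of these 17 passed.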

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

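The tests of the 3 patterns weighed first below were chosen after the result was seen, and the counts over other splits of the libraries were planned before. In the first pattern, the libraries labelled day 3 lay nearer to control than those labelled day 1 in denervation-linked genes such as Chrng and Myh3. Not all such genes did so. Myog, Hdac4 and Cdkn1a rose 6.66-fold, 3.1-fold and 2.66-fold at labelled day 3, against 5.94-fold, 2.23-fold and 1.39-fold at labelled day 1. Of 529 genes that moved one way from control through days 5, 7 and 14, 86.6% lay farther from control in the libraries labelled day 1, as an exchange of the 2 labels would give. Exchanging the labels made 15.3% of them move one way through all times, against 2.08% as labelled. Dilution of the fibres by other tissue in the libraries labelled day 1 would lower fibre genes there. Of 15 muscle-fibre genes that rose at day 14, 14 were higher there than in the libraries labelled day 3. The median difference over the 15 was 1.51 (log2, −2.76 to 6.29), which argues against dilution for these genes. They include Chrng and Myh3, which belong to the pattern itself, so the test is not independent of it. Genes that fell were not tested for dilution. A true early peak that recedes by day 3 could not be told from an exchange, since label and time are one variable, and the labels were kept.

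In another pattern, lymphoid genes were high in the libraries labelled day 1 and day 5 alone. Of 24 genes of lymphoid tissue, 19 were at least 4-fold above control at both days, 5 at day 3 and 0 at day 7 and at day 14, which lymph node or similar tissue collected with the muscle could give. Blood was excluded as the source at day 5, where erythroid markers were below control (median log2 −1.61). At day 1 erythroid and lymphocyte markers were raised together (median log2 1.97 and 5.27), so blood was not excluded there. At day 14 erythroid markers were raised (median log2 1.5) and lymphocyte markers were not (median log2 0.09). That argues against blood at day 1 only if blood held the same share of lymphocytes at both times. The B and T cell genes among the 24 would rise with lymphocytes from any source. Of 6 vessel and stromal genes of lymphoid tissue, 5 were raised too, which argues against lymphocytes alone but does not exclude them. The 6 were listed after the pattern was seen. Glycam1, one of the 5 raised, belongs to the pattern itself, so the test is not independent of it. Among the 5, Chst4 and Madcam1 reached at most 1.43 and 1.62 CPM. Cxcl13 and Ccl19 were also raised at day 3 (log2 2.88 and 1.83), where lymphocyte markers were not.

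In the last pattern, libraries of a group differed by very little. At most 4 genes of a group with a mean CPM of at least 20 differed 2-fold or more between libraries, which is within what was set for libraries made from one RNA source. The control group holds values against one source: Postn was 42.5, 224, 41.8 and 260 CPM in replicates 1 to 4, and Myh6 and Spp1 were also higher in replicates 2 and 4 than in 1 and 3, so this explanation is left open. No pair of libraries held the same counts, since the lowest mean chi-square per gene was 2.02. Repeated sequencing of one library was not excluded, because this measure takes each count as an independent read. Its median over the expected value was 1.86 to 2.55 over the 36 pairs within groups, an excess present in every pair. No biological explanation was tested for this pattern.

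Over the 35 splits of 4 and 4 libraries, chance assignment of these libraries was excluded for the gene counts of all 9 comparisons. Any 2 distinct sets of very similar libraries would give this. The splits therefore cannot show whether groups differ by denervation or by animal, dissection or batch. The real splits gave 10239, 9500, 10195, 10577 and 10269 genes at days 1, 3, 5, 7 and 14 and 10259, 10655, 9637 and 7487 between neighbouring times in 2-group fits. Each had 1 split as large, the real one, and 0 genes in the highest other. Over 100 groupings, the real one included, the 13782 genes that differ among the groups met at most 3496, with 1 as large. For list shifts the real split gave the most at day 3 (23 against 21 in the highest other split, 1 as large), day 7 (25 against 17, 1 as large) and day 14 (23 against 20, 1 as large). Chance was not excluded for the number of list shifts at day 1 (22 against 23, 4 as large) and day 5 (22 against 22, 2 as large). At every day the highest other split still gave at least 17 lists. The number of list shifts thus sets the real split apart far less than the gene counts do.

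A sample far from the other 3 of its group was sought in 548 groups of 4 values, and 44 were found where 27.4 arise by chance at 1 in 20. Among libraries these were the total of day 3 replicate 2 (20.32 in units of 1e+06 counts) and the share of the 20 most abundant genes in day 1 replicate 2 (22.9%) and day 3 replicate 4 (24.4%). Among muscle genes, values in CPM were Chrnd 53.7 (day 5 replicate 2), Runx1 9.59 (control replicate 2) and 164 (day 7 replicate 1), Myh3 5.21 (control replicate 4) and Myh2 344 (day 1 replicate 1). Further values were Myh7 51.3 (day 1 replicate 3), Ncam1 5.13 (day 3 replicate 2), Ppargc1a 12.5 (day 7 replicate 3) and Fbp2 1.55 (day 7 replicate 2). Mybpc2 was 10300 (control replicate 2), Chrna2 7.98 (control replicate 4) and 0.053 (day 14 replicate 1), and Chac1 2.22 (day 14 replicate 3). Other genes were Rab27a 5.7 (day 3 replicate 1), Bdnf 1.68 (control replicate 4), Fst 30.7 (day 7 replicate 4) and Col1a1 567 (day 3 replicate 4). Genes near 0 in control were Mup18 and Trdc 0.0834 (control replicate 2), Zfp593os and Arg1 0.0856 (control replicate 1) and Ighg2c 0 (control replicate 4).

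Among list means (log2 CPM), metabolic lists far from their group were nuclear-encoded oxidative phosphorylation 7.76 and mitochondrially encoded subunits 11.2 (day 3 replicate 2), the tricarboxylic acid cycle 7.75 (day 7 replicate 3) and glycolysis 8.4 (day 14 replicate 3). Fibre lists were atrophy-linked ligases 7.29 (control replicate 2), developmental sarcomere isoforms 4.95 (day 3 replicate 4), slow fibre genes 6.95 (day 3 replicate 3) and excitation-contraction coupling 7.59 (day 7 replicate 3). Signalling lists were activin and BMP 4.07 (day 14 replicate 4), p53 targets 5.84 (day 1 replicate 4), ribosomal proteins 8.5 (day 3 replicate 2), inflammatory genes 1.72 (day 7 replicate 3) and immediate early genes 3.74 (day 5 replicate 4). Cell type lists were lymphocytes 3.73 (day 5 replicate 1), fibroblasts 7.79 (day 5 replicate 2), adipocytes 4.97 (day 5 replicate 4), myelinating Schwann cells 4.14 (control replicate 1) and erythroid markers 4.39 (day 3 replicate 2).

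Effects of opposite sign at neighbouring times differed by the edgeR contrast between the times (log2). From day 1 to day 3 the differences were −5.29 for Myh3, −3.18 for Ncam1 and 1.72 for Ppargc1a, and from day 3 to day 5 they were 5.64 for Myh3, 3.4 for Ncam1 and 0.52 for Myh2. From day 5 to day 7 they were 1.14 for Fst and 1.22 for Col1a1, and from day 7 to day 14 0.98 for Myh7. By camera the proteasome list differed by a median of −0.41 from day 5 to day 7, and erythroid markers by −3.94 from day 1 to day 3 and 3.26 from day 7 to day 14. Counts of genes that differed between neighbouring times were 10555, 11017, 9711 and 7355.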

How the results depend on the processing

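All 9 gene counts and the omnibus count stayed within 1.5 times of their value under every scaling, tool and filter, and with each library left out. So did the 5 gene counts that could be run without the libraries labelled day 1 and 3, and the 4 that could be run without those labelled day 1 and 5. This holds for the totals only. With library totals alone far fewer genes were called lower than control and far more higher at each day, as given above. The fold threshold of 2 was the exception for the 9 gene counts and left 3396, 2450, 3411, 3880 and 3315 genes at days 1, 3, 5, 7 and 14 and 2631, 3154, 1972 and 855 between neighbouring times, by its own construction. Leaving out 1 library gave 10360 to 10668 genes at day 1, 9718 to 10024 at day 3, 10358 to 10665 at day 5, 10670 to 11010 at day 7 and 10341 to 10651 at day 14. Between neighbouring times it gave 10323 to 10627, 10778 to 11111, 9365 to 9797 and 6873 to 7396, with 118 to 120 list shifts and 13812 to 13865 genes in the omnibus test, where the filter let in 14366 to 14405 genes. Without the libraries labelled day 1 and 3, counts were 10506, 10863 and 10530 at days 5, 7 and 14, and 2 list shifts were lost, mitochondrial biogenesis at day 5 and tendon at day 14. Without those labelled day 1 and 5, counts were 9884, 10833 and 10557 at days 3, 7 and 14. Of the 390 named values, 41 fell under the 2-fold threshold, and scaling by library totals relative to the median gene moved 9. Cd81 at day 14 lost its call without the expression filter and without the libraries labelled day 1 and 5. With an estimated correlation 97 of the 119 list shifts held and 22 were lost.

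fry, which does not compare a list with other genes, called 188 lists against 119. It gave the opposite direction to camera in 6 lists that camera did not call, with mean ratios of log2 fold change to standard error of 1.036 for the neuromuscular junction, 1.885 for activin and BMP, −3.897 for p53 targets and 2.149 for satellite cells at day 3. The others were −0.386 for fibroblasts at day 7 and 7.067 for p53 targets at day 14, and the cause was not tested. Replicate numbers do not pair samples by design. As a block they gave 10577, 9972, 10574, 10923 and 10589 genes at days 1, 3, 5, 7 and 14, 10520, 11003, 9673 and 7320 between neighbouring times, 13757 in the omnibus test and 119 list shifts, and the block changed no list or named call. Libraries of different groups with one number had a mean correlation of 0.0039 (−0.078 to 0.079 over 60 pairs) after group means were removed, so the data give no hint of pairing. The alternative pseudocount, meant for FPKM, was not run on counts. Depth limits genes near 0 in control, whose folds rest on 0 to 3 counts.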

Other observations

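Circadian clock genes and immediate early genes, 2 lists not yet described, did not pass camera against control at any of the 5 times. Camera tests for a shared direction, so it cannot show that a list is unchanged where members move opposite ways. Members of both lists did so, as given below. From day 7 to day 14 both shifted up by camera, the clock list by a median log2 of 0.47 (adjusted p = 1.4e-05) and the immediate early list by 0.21 (adjusted p = 0.04). Per1, a clock repressor that light and glucocorticoids induce, stood at 126 CPM in control and fell to 14.6 CPM at day 7 (log2 −3.11, n = 4 per group). Npas2, a clock activator, fell at every time and was lowest at day 14 (1.43 against 11.5 CPM). Dbp, a clock output gene, was 76 and 16.5 CPM in the libraries labelled day 1 and day 3 and 154 CPM at day 14, against 22.9 CPM in control. Bmal1, the core clock activator, was 95.4 CPM in the libraries labelled day 3 and 13.9 CPM at day 7, against 47.4 CPM. Camera's adjusted p for the clock list was 0.12, 0.48, 0.082, 0.38 and 0.67 at days 1, 3, 5, 7 and 14. At day 5, 3 of 15 measured members rose, 10 fell and 2 did not pass (4 rose and 10 fell adjusted over the list alone). The hour of collection is not stated in the labels.

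Among immediate early genes, Fos, which responds to activity and handling, was 111 CPM in control and fell to between 7.86 and 12 CPM in the denervated groups. Whether Fos was raised in the control libraries, which all these comparisons share, was not tested. Egr1 fell from 134 CPM to 15 CPM at day 5 (log2 −3.16). Atf3, a stress-induced factor, rose at every time and most in the libraries labelled day 3 (6.77 to 98.3 CPM), as did Nr4a3 (0.998 to 53.8 CPM). The list's adjusted p was 0.067, 0.26, 0.14, 0.099 and 0.16 at the 5 times.

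Some genes differed among control libraries by far more than counting noise. Postn was 42.5, 224, 41.8 and 260 CPM in control replicates 1 to 4, Myh6 1.37, 19, 0.964 and 22 CPM, and Spp1 10.1, 20.2, 7.63 and 19.9 CPM. Folds of these genes against control average unlike libraries.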
